A study of Mus musculus with 4 samples.

How the data were processed

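Synovial CD45+CD11b+Ly6G- cells were profiled with the Chromium Single Cell 3' v2 kit, which counts unique molecular identifiers (UMIs) near the 3' ends of transcripts, with 17400 cells loaded per sample per the labels' protocols. The deposited files hold UMI counts per gene and barcode, whole numbers that were not normalized. Per the submitters' processing notes, Cell Ranger 2.1.0, Seurat 2.3 and R 3.5.2 were used with the mm10 build, and which step each performed is not given in the sources used here. Each file lists only genes found in at least 5 of its barcodes, so an unlisted gene is not a value of 0. The libraries list 11413, 12527, 12047 and 12446 genes at days 0, 1, 2 and 5. Day and library cannot be told apart, since each day has 1 library, and the labels do not say how many mice entered each.

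Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept. Scrublet (in scanpy 1.11.5) was run per library with an expected rate of 0.8% per 1000 cells. It called 0, 1, 6 and 6 doublets, 0.0908% of cells, and so has not worked on these data. The called cells were removed and doublets otherwise remain. Cells were clustered together on log-normalized counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). TdTomato and the tight junction and polarity list were kept out of the variable genes. Integration was not used, since day and library cannot be separated. A cluster was named from marker genes when at least 3 of a class were raised (log2 ratio of at least 0.5, with 20 CPM added), that class had the highest mean, it had at least 1 marker among the first 10 genes by ratio, and no other class had more there. This scoring, and leaving erythroid cells out of the names because haemoglobin RNA led a cluster whose other leading genes went against that name, were set after the data were seen. MHC class II-high clusters include some led by Cd209a, a dendritic cell gene.

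UMIs were summed over the retained cells of a library or class and given as CPM, counts scaled to the same total in each. Ratios carry exact conditional Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals. A count of 0 was set to 3 counts in ratios. Genes listed in both libraries with at least 10 CPM in 1 of them counted as measured members of a list. A list's median log2 ratio was placed among 10000 random lists of equal size matched in 20 bins of expression, with an interval from 1000 Poisson draws. Named genes had at least 50 CPM in 1 library and a ratio of at least 2, ranked by log2 of CPM with 5 added. The first 10 in each direction were named, apart from mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes, with up to 4 members of each list taken from those with the largest ratios. Some results that met these rules are not reported here. The comparison of lining-like cells with day 0 and the day 0 junction comparison could not use the joint clustering. The first was replaced by comparisons with day 1, and the second used the day 0 library clustered alone, both after the data were seen. For cycling cells, each cell was thinned to 500 UMIs, which left out no retained cell.

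Alternatives set before the data were opened were other gene minimums (200 for shares and 1000), a 5% mitochondrial limit, doublets kept, resolutions 0.5 and 2.0, 15 components, each library clustered alone for shares, median-ratio scaling, the mean of each cell's CPM, no filter on low values, the junction list left in the variable genes, and for cycling cells no thinning and at least 2 UMIs. Ratios and list medians were tested on counts simulated for day 5 against day 0 over 6768 genes. All 200 genes changed 4-fold (100%) were recovered past 2-fold, 0.0152% of unchanged genes passed it, 95.6% of intervals held the true ratio, and 3% of unchanged lists lay outside the central 95%. The counts were drawn from a Poisson distribution for each gene independently, as the intervals assume. Genes that vary together and spread between animals or libraries were not simulated, so the percentiles of real lists were not tested. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.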

Results

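Single-cell RNA was measured in mononuclear myeloid cells of the hind paw synovium, the tissue that lines the joint, in a serum-transfer model of arthritis. K/BxN serum carries autoantibodies that cause arthritis in recipient mice. The mice were Cx3cr1creER:tdTomato mice given tamoxifen 4 weeks before the serum, which switches on the red fluorescent reporter tdTomato in cells that express Cx3cr1 at that time and leaves it on in their descendants. CD45+CD11b+Ly6G- cells, a gate that leaves out neutrophils, came from steady state (day 0) and from 1, 2 and 5 days after serum transfer. There was 1 library per day, so no difference between days has a replicate check and no test was made. Intervals are 95% intervals that cover counting error only.

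The day 0 library differed from the others in depth. It held 7542 barcodes with a median of 832 UMIs, against 4674 barcodes and 3594 UMIs at day 1, 2756 barcodes and 4158.5 UMIs at day 2, and 3265 barcodes and 3888 UMIs at day 5. The total was 7115082 UMIs at day 0, 18426363 at day 1, 12218230 at day 2 and 14995823 at day 5. The minimum of 500 genes per cell removed 3760 barcodes (49.9%) at day 0 and 1, 2 and 0 at days 1, 2 and 5. The retained cells numbered 3715, 4641, 2716 and 3229 at days 0, 1, 2 and 5.

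The first comparison asked which classes of cell were present in the joint on each day. Cells with markers of blood monocytes (Ly6c2, Plac8, Chil3) were rare at days 1 and 2 and were the largest named class of day 5 in the joint clustering, though not with each library clustered alone. Cells with Spp1 and Arg1, genes of wound-type macrophages, also had their largest share at day 5. Cells of the bone-resorbing osteoclast lineage (Acp5, Ctsk, Mmp9) had shares whose order over the days depended on the settings. Monocyte-like cells held 24.1% (interval 22.6 to 25.6%) at day 5, against 0.668% (0.454 to 0.947%) at day 1 and 1.22% (0.838 to 1.70%) at day 2. Arg1-like cells held 0.560% (0.366 to 0.820%), 0.6996% (0.422 to 1.09%) and 12.1% (11.03 to 13.3%) at days 1, 2 and 5, and haemoglobin genes were also among the leading genes of their cluster. Osteoclast-like cells held 0.237% (0.118 to 0.424%), 0.221% (0.0811 to 0.480%) and 3.53% (2.92 to 4.23%) on those days, and 4.71% at day 0 in a cluster almost wholly of that library. Their day 5 share was 0 with a mitochondrial share under 5% and at resolution 0.5, and 0.793% without the cells of highest Scrublet scores, and at day 2 it was 7.88% with each library clustered alone. With 15 principal components the day 5 shares were 14.5% monocyte-like, 9.14% osteoclast-like and no Arg1-like cells, and with each library clustered alone they were 15.8%, 0.805% and 11.9%. Clustering alone also gave 0.905% and 1.84% monocyte-like cells at days 1 and 2.

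Lining-like cells were defined by Sparc, Vsig4, Olfml3 and Cx3cr1, genes of the macrophages that cover the synovial surface. They held 23.3% (22.1 to 24.6%), 24.3% (22.7 to 26.0%) and 15.1% (13.9 to 16.4%) at days 1, 2 and 5. An unnamed cluster (number 7), with the immediate early genes Nr4a1 and Atf3 among its leading genes, also had all 7 lining markers raised and held 3.32%, 9.83% and 6.04% of cells on those days. It was kept out of the class by a condition set after the data were seen, and with it the shares were 26.6%, 34.2% and 21.2%. Clustering each library alone gave 14.8%, 23.0% and 21.8%, so the order of the days depended on the clustering. Retnla-like cells, with Mrc1, Cd163 and F13a1 of tissue-resident macrophages, held 33.3% (32.0 to 34.7%), 20.7% (19.1 to 22.2%) and 11.8% (10.7 to 12.96%) at days 1, 2 and 5, and 15.8%, 15.5% and 21.9% with each library clustered alone. The same condition kept unnamed clusters 6 and 14 out of this class, and with them the shares were 40.6%, 32.9% and 17.2%. MHC class II-high cells, which carry the genes for presenting antigen to T cells, held 16.0% (14.99 to 17.1%), 12.8% (11.6 to 14.1%) and 8.49% (7.55 to 9.50%), and no cluster of day 2 alone took that name. Unnamed clusters held 23.8%, 38.0% and 21.1%.

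**Figure D1:**
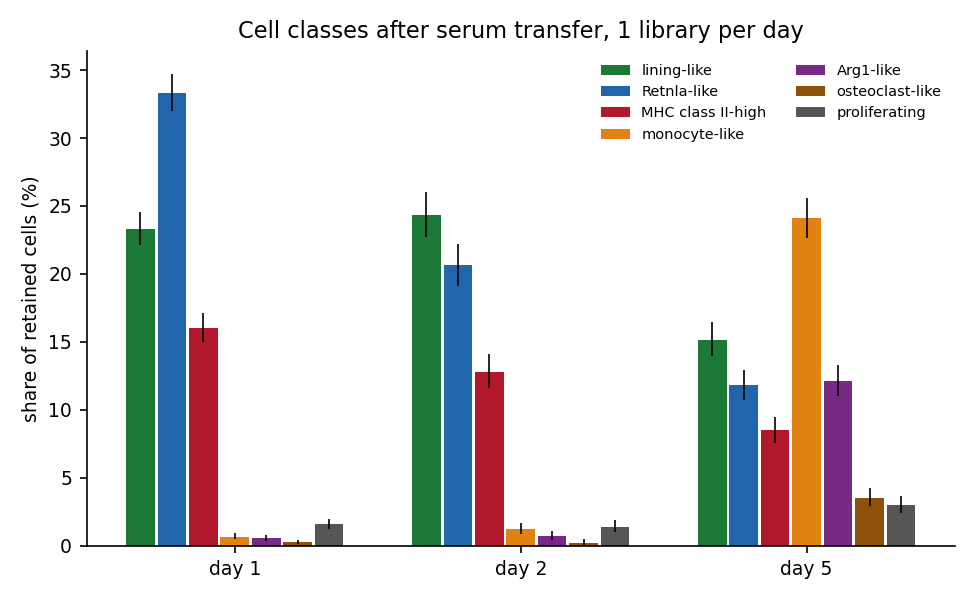
Share of retained cells (percent, y axis) in each named class at days 1, 2 and 5 (x axis), from the joint clustering, with exact Clopper-Pearson 95% intervals as lines on the bars and 1 library per day. Monocyte-like cells stand at 24.1% at day 5 and at 0.668% and 1.22% at days 1 and 2.

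Day 0 could not be placed in these classes by the joint clustering. Of its 3715 cells, 3269 fell into a cluster (number 0) that took no class name and held 40, 93 and 7 cells of days 1, 2 and 5, and 1 cell was lining-like. A cluster mostly of 1 library can be that library rather than a cell type. With the day 0 library clustered alone, 18.1% (16.9 to 19.4%) of cells were lining-like, 20.3% (19.0 to 21.6%) MHC class II-high, 4.60% (3.95 to 5.33%) proliferating and 3.88% (3.28 to 4.55%) osteoclast-like. No cluster took the monocyte-like name, which sets no bound on such cells, since names go to whole clusters and the smallest held 22 cells (0.592%). Unnamed clusters held 52.2%, among them 1 led by Aqp1 and Fxyd2 with 25.5% and 1 led by the chemokines Ccl8 and Ccl7 with 16.9%. Aqp1 was among the markers used to name MHC class II-high cells, whose share leaves that cluster out. In the joint clustering, osteoclast-like cells of day 0 also held 71 genes that those of day 5 lack, at a median of 0.694 of the library level. The source of this RNA was not settled.

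**Figure D2:**
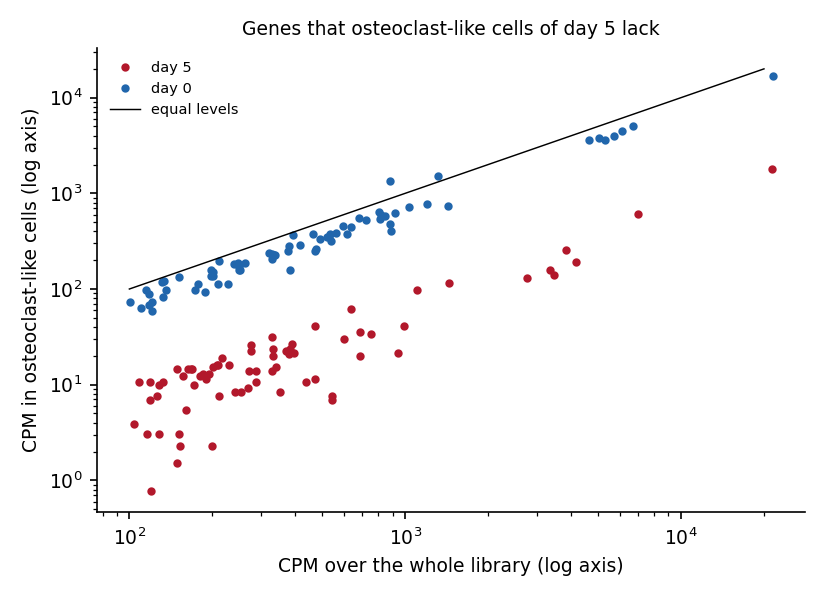
Level in osteoclast-like cells (CPM, y axis, log scale) against the level over the whole library (CPM, x axis, log scale) for 71 genes that osteoclast-like cells of day 5 hold at under 10% of their library level, at day 5 and at day 0, with a line of equal levels. The cells of both days come from the joint clustering. Day 0 cells hold these genes at a median of 0.694 of the library level.

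The transcript of the reporter, TdTomato, marks cells that expressed Cx3cr1 when tamoxifen was given and their descendants. It was highest in lining-like cells among the named classes on every day, and low in monocyte-like and osteoclast-like cells of day 5. Cx3cr1 was also among the markers that named lining-like cells, so this ranking is not independent of the naming. Over the whole libraries TdTomato stood at 878 CPM (849.9 to 906) at day 0, 583 (572 to 594) at day 1, 774 (758 to 789.8) at day 2 and 379 (369 to 389) at day 5 (CPM, UMI counts scaled to the total of the library or class). Lining-like cells held it at 1174 CPM (1145 to 1204) at day 1, 1225 (1188 to 1263) at day 2 and 1119 (1076 to 1163) at day 5, with at least 1 UMI in 92.1%, 95.3% and 95.3% of cells. Monocyte-like cells of day 5 held 88.9 CPM (78.9 to 99.7), 12.6-fold (11.1 to 14.3) less than lining-like cells, with a UMI in 21.2% of cells, at median depths of 3819.5 and 4428 UMIs. Osteoclast-like cells of day 5 held 73.0 CPM, 15.3-fold (12.5 to 19.0) less, and Arg1-like cells 73.2 CPM, 15.3-fold (12.6 to 18.7) less. With each library clustered alone, monocyte-like, Arg1-like and osteoclast-like cells of day 5 held 110, 80.7 and 123 CPM, the last in 26 cells. Lining-like cells then held 1187 CPM. No background level of TdTomato was measured, so the low levels of these classes may be a floor and not their own expression. Retnla-like cells held 199, 278 and 181 CPM at days 1, 2 and 5, which was 5.91-fold, 4.41-fold and 6.20-fold less than lining-like cells. With each library clustered alone they held 172, 279 and 287 CPM, against 1213, 1205 and 1187 CPM in lining-like cells. The cells of cluster 7 held 1516, 1533 and 1414 CPM. At day 0, with that library clustered alone, lining-like cells held 1353 CPM (1274 to 1435) and osteoclast-like cells 606 CPM (494 to 735), a 2.23-fold difference (1.82 to 2.76). In the joint clustering, where 175 osteoclast-like cells of day 0 held TdTomato at 657 CPM, genes that those of day 5 lack were also examined. In the day 0 cells these genes stood at a median of 0.694 of the library level. This leaves open whether the TdTomato of the day 0 cells is their own, so the day 0 difference is not compared with that of day 5.

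**Figure D3:**
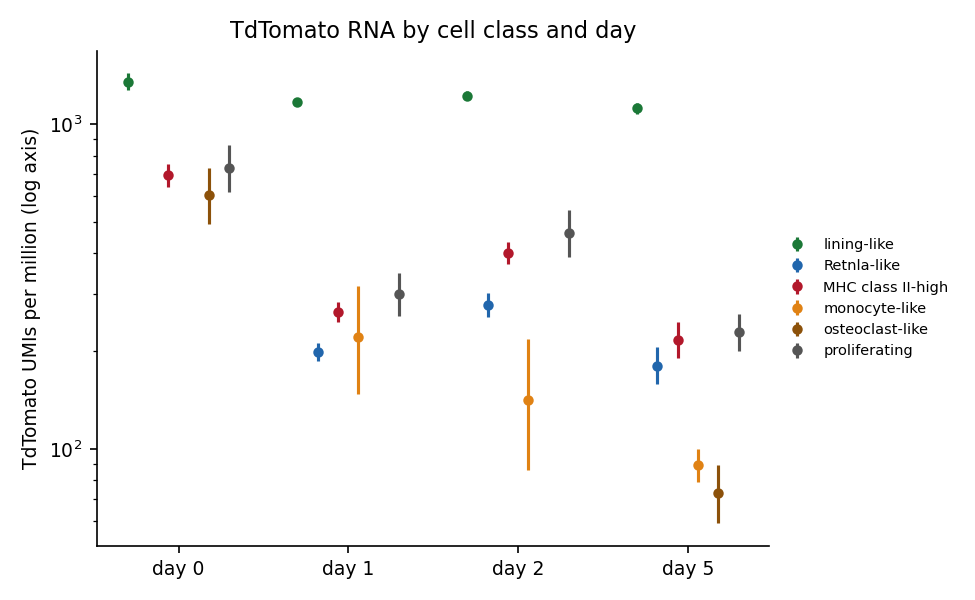
TdTomato CPM (y axis, log scale) summed over the cells of each class on each day (x axis), with exact Poisson 95% intervals; the classes of day 0 come from that library clustered alone and those of the other days from the joint clustering. Lining-like cells stand highest among the drawn classes on every day, at 1119 to 1353 CPM.

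The second comparison set the whole library of each day against day 0. These ratios, and the list medians made from them, mix the share of each cell class with expression inside the classes. The contributions were not separated, so a ratio need not be a change inside any class. The first 10 higher genes of day 5 included Plac8, Hp and F10, which were among the monocyte markers used to name clusters. Hp encodes the haemoglobin-binding protein haptoglobin. Others were Ifitm1, which encodes an interferon-induced membrane protein, and Thbs1, which encodes the matrix glycoprotein thrombospondin-1. Ifitm1 was also among the dendritic cell markers used to name clusters. Ifitm1 was 85.4-fold (56.8 to 135) higher, Thbs1 229.5-fold (89.6 to 843), Plac8 48.3-fold (35.1 to 68.3) and Hp 88.4-fold (46.5 to 194). Dmkn, a secreted protein of skin, was 277-fold (76.6 to 2291) higher, Slpi, a protease inhibitor, 131-fold (44.7 to 635), and F10, coagulation factor X, 77.8-fold (30.3 to 286). The cystine transporter Slc7a11 was 46.9-fold (22.7 to 117) higher, and the membrane protein genes Ms4a4c and Sirpb1c 39.0-fold (25.9 to 61.6) and 29.97-fold (19.9 to 47.4). Several of these rest on few day 0 counts, such as 2 for Dmkn, 3 for Slpi and 4 for Thbs1. With at least 1000 genes per cell, which left 96 cells at day 0, Ifitm1, Thbs1, Plac8, Hp, Dmkn, Slpi and F10 had no UMI at day 0, so their ratios are lower bounds set by the number of cells. With that count of 0 set to 3, the bounds for Ifitm1, Thbs1, Hp, Dmkn, Slpi and F10 were 39.4, 18.0, 15.8, 10.96, 7.63 and 6.12. The ratio of Slc7a11 was 19.4, on 1 UMI at day 0. With at least 200 genes those of Dmkn and Slc7a11 were 177 and 29.2.

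At days 1 and 2 the highest ratios among genes of at least 50 CPM were far smaller. Of these genes Cx3cr1, the chemokine receptor whose promoter drives the Cre, led on both days, at 3.02-fold (2.62 to 3.501) higher at day 1 and 3.86-fold (3.34 to 4.47) at day 2. At lower levels, Oasl2, an interferon response gene, was 4.38-fold higher at day 1 and Hp 8.62-fold higher at day 2. Also in the first 10 on both days were Abca9, a transporter (2.93-fold and 2.54-fold), Chd9, a chromatin remodeller (2.57-fold and 2.83-fold), Dnajc13, an endosomal chaperone (2.46-fold and 2.63-fold), Eno1, a glycolytic enzyme (2.295-fold and 2.37-fold), and Dcn, the matrix protein decorin (2.72-fold and 2.46-fold). Dcn is a fibroblast gene, and the fibroblast markers together stood at 45.5, 124, 95.3 and 102 CPM at days 0, 1, 2 and 5. Day 1 also had the lipase Lpl (2.55-fold), Dock2, which acts in leukocyte migration (2.55-fold), and the actin-binding Cnn2 (2.37-fold) and Tmsb10 (2.24-fold). Day 2 also had the integrin Itgb5 (2.66-fold), the collagen chaperone Serpinh1 (2.54-fold) and the scaffold protein Iqgap2 (2.49-fold). The ratios of day 1 with at least 1000 genes per cell were 5.59 for Dcn, 1.12 for Dock2 and 1.40 for Dnajc13, and at day 2 4.99 for Dcn, 5.23 for Serpinh1 and 1.49 for Dnajc13, on 4, 15, 3 and 11 UMIs of Dcn, Dock2, Serpinh1 and Dnajc13 at day 0.

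The 3 days share 1 day 0 library as their reference, so anything peculiar to that library would make the same genes lower on each day. Slc39a1, a zinc transporter, stood at 625 CPM at day 0 and at 84.0, 95.7 and 95.5 CPM at days 1, 2 and 5. Notch2, a cell-contact receptor, was 6.32-fold, 6.05-fold and 7.52-fold lower. The LIM-domain gene Fhl3, the sterol regulator Insig1, the hydrolase Abhd2 and the peptide-amidating enzyme Pam were also in the first 10 lower genes on each day, at 5.96-fold to 9.18-fold lower. Pim1, a kinase, and Kdm6b, a histone demethylase, were 7.24-fold and 7.26-fold lower at day 1, with the transcription factors Hsf2 (8.09-fold) and Bhlhe41 (5.84-fold). At day 2 Pim1 (5.17-fold), the translation genes Eif3f (6.21-fold) and Paip1 (5.69-fold) and the RNA demethylase Alkbh5 (5.51-fold) joined them. At day 5 Cxcl13, a B cell-attracting chemokine, was 14.7-fold (12.98 to 16.6) lower, Bhlhe41 10.95-fold, the transcription factor Nfia 6.73-fold and Alkbh5 5.54-fold. Relative to day 0, the levels with at least 1000 genes per cell were 0.244, 0.219 and 0.237 for Abhd2, 0.246 for Hsf2 at day 1, and 0.295 and 0.309 for Alkbh5 at days 2 and 5. Retained day 0 cells had a median of 1057 UMIs, against 3607, 4178.5 and 3895 at days 1, 2 and 5. Scaling by median ratios moved the median gene by -0.17, -0.15 and -0.10 on the log2 scale at days 1, 2 and 5.

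Against that same library, the medians of the monocyte and interferon lists were above 0 and that of the chemokine list below 0 on all 3 days, and that of inflammatory mediators was above 0 at day 5 alone. Monocyte recruitment genes were the monocyte markers used for naming plus S100a4, S100a6 and Itga4. They had a median log2 ratio of 0.77 (0.60 to 0.88), 0.81 (0.64 to 1.30) and 3.31 (3.002 to 3.52) at days 1, 2 and 5, and 0.60, 0.66 and 3.20 under median-ratio scaling. The day 1 median leaves out Hp and F10, which missed the 10 CPM limit. They stood at 6.59 and 2.07 CPM at day 1 and at 2.07 and 0.920 CPM at day 0. At least 2-fold higher were 1 of 6, 4 of 9 and 7 of 10 measured genes, led at day 5 by Hp, F10 and Plac8, with the chitinase-like Chil3 at 22.6-fold. Proinflammatory mediators had medians of -0.86, -0.041 and 1.75, or -1.03, -0.19 and 1.65 under that scaling. At day 5, 5 of 8 were at least 2-fold higher, among them Ptgs2, the inducible cyclooxygenase (12.7-fold; 7.21 to 24.7), the cytokine gene Il1b (11.8-fold; 10.7 to 13.02) and the cytokine gene Osm (5.19-fold). With no filter on low values that day 5 median was 0.90, and the day 2 median was 0.030 when each cell was weighted equally and -0.28 with at least 1000 genes per cell. Neutrophil markers stood at 48.4 CPM at day 5 and 20.01 CPM at day 0. At day 1 Tnf, a central inflammatory cytokine, was 3.86-fold lower and Tnfsf9, a costimulatory ligand, 2.76-fold lower. Chemokines, which draw leukocytes into tissue, had medians of -1.65, -1.11 and -1.28, or -1.82, -1.25 and -1.38 under median-ratio scaling. At least 2-fold lower were 11 of 16, 9 of 16 and 10 of 17, with the T cell attractant Ccl5 20.1-fold lower at day 1, Cxcl10 3.93-fold lower at day 2 and the monocyte attractant Ccl12 4.74-fold lower at day 5. NK or T cell markers stood at 9.66 CPM at day 0, and none was listed at day 1. Cxcl3, a neutrophil attractant, was 5.75-fold higher at day 5. Immediate early and stress genes, which also respond to cell handling, had a median of -0.48 (-0.53 to -0.41) at day 1, below all of 10000 matched random lists, or -0.65 under median-ratio scaling and -0.72 with at least 1000 genes per cell, with Ier3 3.499-fold lower. Among 10000 random lists matched on expression, the monocyte recruitment median lay at the 99.99, 99.99 and 100 percentile at days 1, 2 and 5, and the chemokine median below all of them on each day.

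Interferon response genes, which cells switch on after sensing type I interferon, had medians of 0.70, 0.85 and 1.99 at days 1, 2 and 5. At least 2-fold higher were 3 of 7, 4 of 8 and 8 of 9, such as, at day 5, Oasl2 (6.83-fold; 4.01 to 12.6) and Ifitm3 (5.17-fold; 4.90 to 5.47). Matrix remodelling genes had a median of 0.53 at day 5 and 0.18 when each cell was weighted equally, with the protease inhibitor Timp1 at 18.6-fold (11.7 to 31.6) and the collagenase Mmp13 at 15.6-fold. Glycolysis and hypoxia genes stood at 0.62, with Eno1 at 3.09-fold and the oxygen-sensing factor Hif1a at 2.74-fold. Lipid handling genes stood at 0.41, and at 0.19 with at least 1000 genes per cell, with Spp1, osteopontin, at 10.4-fold (9.50 to 11.4) and the lipid droplet gene Plin2 at 2.81-fold. Cell cycle genes stood at 0.88, with Top2a, which untangles replicated DNA, at 4.64-fold, but at -0.048 when each cell was weighted equally. MHC class II genes stood at 0.57 (H2-DMb1 1.86-fold higher), and Fc receptor genes, which bind antibody, at 0.29 with Fcgr1 3.14-fold higher, or 0.18 under median-ratio scaling.

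Resident macrophage genes stood at -0.52 at day 5, with Lyve1, a hyaluronan receptor, 2.21-fold lower and the haemoglobin scavenger receptor Cd163 1.87-fold lower. At day 1 they stood at 0.43 (0.26 under median-ratio scaling). Complement genes stood at -0.40 at day 5, with C1qc 1.58-fold lower and the central component C3 9.92-fold higher, and at 0.32 at day 1 (0.15 under that scaling). Iron handling genes stood at -0.33 at day 5, with the haem-degrading Hmox1 2.096-fold lower, and at -0.18 when each cell was weighted equally. Efferocytosis genes, for the uptake of dead cells, stood at -0.24, with the interleukin-1 antagonist Il1rn 5.88-fold higher, and at -0.12 when each cell was weighted equally. The CSF1 axis, which sustains macrophages, stood at -0.053 (the cytokine receptor Csf2rb 2.60-fold higher), and at 0.0011 and -0.31 with at least 200 and 1000 genes per cell. Immediate early and stress genes stood at -0.088 (the heat shock gene Hspa1a 2.13-fold lower), at -0.19 under median-ratio scaling, at -0.27 with at least 1000 genes per cell and at 0.10 when each cell was weighted equally. Tight junction and polarity genes stood at 0.078 and turned to -0.027 under median-ratio scaling, and were at 0.18 with at least 1000 genes per cell, with the adhesion gene Ctnna1 1.06-fold higher. That scaling moves all genes of a day alike, by -0.17 and -0.15 at days 1 and 2, so medians between 0 and that shift change sign by arithmetic. At day 1 these were glycolysis and hypoxia (0.092 to -0.079), efferocytosis (0.088 to -0.083), matrix remodelling (0.078 to -0.12), iron handling (0.14 to -0.033) and cell cycle (0.13 to -0.087), and at day 2 iron handling (0.038 to -0.11), cell cycle (0.095 to -0.050) and immediate early genes (0.11 to -0.036). Matrix remodelling and cell cycle at day 1 moved further than the shift, since fewer members then passed the 10 CPM limit.

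**Figure D4:**
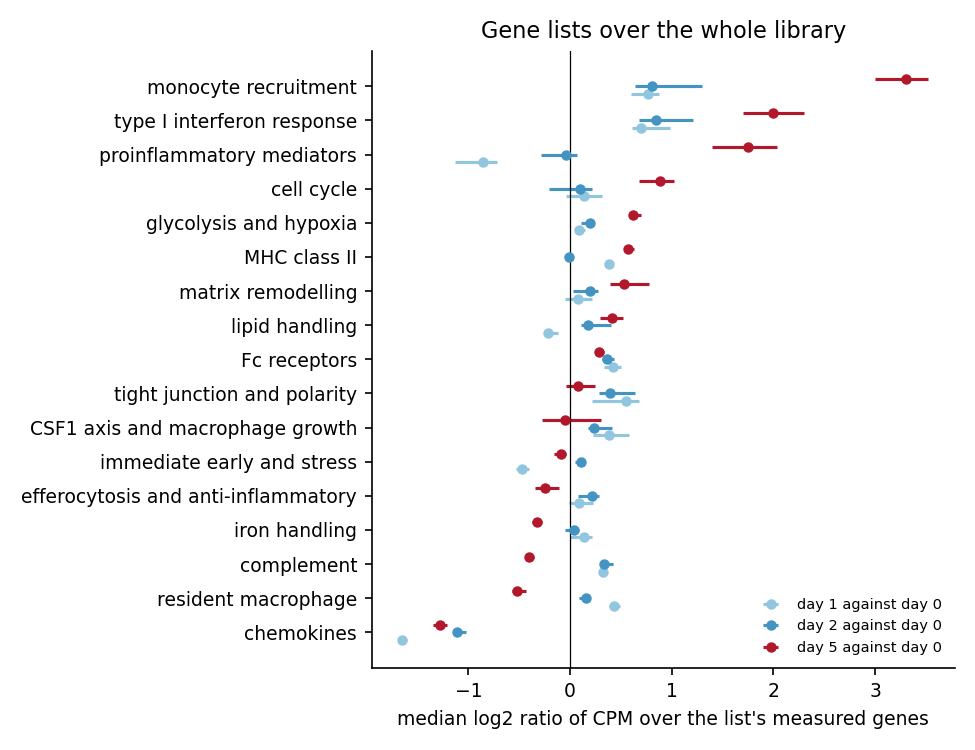
Median log2 ratio of CPM against day 0 (x axis) for each gene list (y axis) over the whole libraries of days 1, 2 and 5, with 95% intervals from Poisson draws of the counts. Monocyte recruitment stands at 3.31 at day 5, and chemokines stand below 0 on each day.

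The third comparison looked inside lining-like cells. It was not made against day 0 as designed, since the joint clustering left 1 lining-like cell at day 0, and days 2 and 5 were set against day 1 instead, a choice made after the data were seen. Few genes passed the rule for named genes, which asks for at least 50 CPM, and none of those was lower. The class leaves out cluster 7, which had the lining markers raised and held 154, 267 and 195 cells at days 1, 2 and 5, against 1082, 661 and 489 in the class, so the values stand for a part of such cells that differs by day. Cxcl2, a neutrophil-attracting chemokine, was 2.49-fold (2.04 to 3.06) higher at day 2 and 2.99-fold (2.42 to 3.70) at day 5, and 1.61-fold at day 2 with at least 200 genes per cell. At day 5, the secreted protein gene Retnla was 3.34-fold (3.09 to 3.61) higher, the transcription factor Cebpd 2.31-fold (1.85 to 2.89), the translation factor Eif3f 2.09-fold (1.87 to 2.34) and Spp1 2.07-fold (1.84 to 2.33). Retnla with at least 1000 genes per cell was 1.91-fold and Spp1 1.199-fold higher. Below that level, and on few UMIs, the chemokine gene Cxcl13, at 20.9 CPM at day 1, was 14.1-fold lower (5.86 to 44.3) at day 2 and 47.8-fold lower (8.41 to 1907) at day 5, and Ccr2, a receptor that brings monocytes into tissue, 2.99-fold lower (1.66 to 5.76) at day 2. The chemokine gene Ccl8 was 2.25-fold higher (1.57 to 3.26) at day 2. Il1b stood at 28.9 CPM in lining-like cells of day 5 and 4.07 CPM in those of day 1, against 1119 and 54.1 CPM over the whole libraries. Of 12 resident macrophage genes, 1 (Retnla) was at least 2-fold higher at day 5, and the median was -0.047.

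The last comparisons concerned the barrier and the renewal that the title of the series names. Tight junction and polarity genes were compared between lining-like cells and those named Retnla-like or MHC class II-high, with the list kept out of the clustering. The MHC class II-high class includes clusters led by the dendritic cell gene Cd209a. Its day 0 cluster was led by Ccl17, which was among the mature dendritic cell markers, so the reference need not be macrophages alone. F11r, which encodes the junctional adhesion molecule JAM-A, was higher in lining-like cells on every day, while the adhesion gene Ctnna1 was not. Few of the 21 genes of the list were measured, 3 at day 0 and in the joint clustering, and 4 and 2 at days 1 and 2 with each library clustered alone. At day 0, in the library clustered alone, F11r stood at 169 CPM in 673 lining-like cells and 89.1 CPM in 754 MHC class II-high cells, a 1.89-fold difference (1.42 to 2.53). F11r was among the genes that osteoclast-like cells of the joint clustering held at day 0 and lacked at day 5, at 0.576 of the day 0 library level. RNA shared between barcodes would bring the F11r ratio nearer to 1, so it is not compared with later days. Ctnna1 stood at 1.02-fold (0.722 to 1.44). The list median was 0.030 (-0.36 to 0.93), and 1.00 at resolution 2.0. At days 1, 2 and 5, F11r was 4.54-fold (4.07 to 5.07), 3.76-fold (3.26 to 4.34) and 4.34-fold (3.63 to 5.21) higher in lining-like cells than in Retnla-like and MHC class II-high cells, while Ctnna1 stood at 0.754-fold, 0.807-fold and 0.841-fold. With each library clustered alone F11r was 3.65-fold and 3.87-fold higher at days 1 and 5, and 6.76-fold at day 2, where the reference was 420 Retnla-like cells without MHC class II-high cells. Jam2, which encodes another junctional adhesion molecule, was 2.72-fold (1.58 to 4.77) higher at day 1 in that run.

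Dividing cells bear on renewal in place. After thinning every cell to 500 UMIs, 11.5% (10.5 to 12.5%) of cells at day 0 had at least 1 UMI of the cell cycle list, against 8.47% (7.68 to 9.31%) at day 1, 8.69% (7.66 to 9.81%) at day 2 and 10.3% (9.23 to 11.3%) at day 5. Without thinning the shares were 22.2%, 41.7%, 44.5% and 45.9%. The list held 287, 303, 271 and 467 CPM, an order that differs from that of the thinned shares, so no order of the days is read from them. Lining-like cells stood at 5.55% (4.26 to 7.08%), 5.60% (3.97 to 7.63%) and 6.13% (4.18 to 8.64%) at days 1, 2 and 5, and monocyte-like cells of day 5 at 6.56% (4.92 to 8.53%), and no background level was measured. Osteoclast-like cells of day 5 stood at 29.8% (21.6 to 39.1%), at a median of 8737.5 UMIs against 3895 in their library, in a class that is lost or far smaller in some of the settings given above. Clusters of proliferating cells held 5.01% (4.33 to 5.76%) of cells at day 0, 1.59% (1.25 to 2.00%) at day 1, 1.40% (0.992 to 1.92%) at day 2 and 2.97% (2.41 to 3.62%) at day 5. The day 0 share with at least 1000 genes per cell was 1.04%, of only 96 cells. The proliferating cells of day 0 formed a cluster of their own (number 12), apart from the cluster that held most of those of the other days (number 11).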

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

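All of the tests in this part were chosen after the results were seen, and the limits for inner A runs and for transcript length and GC were rewritten after their values were seen, from limits that would have excluded these explanations to limits that leave them open with 13 genes.

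Gene lists whose median log2 ratio to day 0 had opposite signs at days 1 and 5, with neither interval reaching 0, were proinflammatory mediators (-0.86 and 1.75), complement (0.32 and -0.40), lipid handling (-0.22 and 0.41) and resident macrophage genes (0.43 and -0.52). Opposite signs with 1 of the 2 intervals reaching 0 were found for efferocytosis (0.088 and -0.24), iron handling (0.14 and -0.33) and the CSF1 axis (0.39 and -0.053). These differences were not tested, with 1 library per day. With at least 1000 genes per cell the lipid handling median of day 1 was 0.21.

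Signal also stood outside the retained cells. Day 0 barcodes under 500 genes held TdTomato at 839 CPM and Vsig4 at 1474 CPM. Haemoglobin genes stood at 0 CPM at day 0, 29.2 at day 1, 5.20 at day 2 and 162 at day 5, and day 0 lists none of them, which is not a measured 0.

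Osteoclast-like cells of day 0 in the joint clustering held genes of other classes. Doublets with lining cells would add UMIs, but the median UMIs of these cells were 0.998 of their library's. The 71 genes that osteoclast-like cells of day 5 lack stood at a median of 0.694 of the library level at day 0, with an upper to lower quartile ratio of 1.202, which is what RNA free in the suspension would give, and other mixing of RNA between barcodes stays open. In fibroblast-like cells 53 genes of the same kind had a median of 0.863 but a wide spread, from Acp5 at 0 to Mgl2 at 2.74. Evenly free RNA alone would not give that spread. The class held only 27 cells with 36850 UMIs at day 0 and 19 cells at day 5, so counting error also widens it. A biological difference between day 0 and day 5 cells was not tested.

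At day 0, 13 genes stood at least 4-fold above each other day, a limit chosen after the data were seen, among them Slc39a1, Notch2, Insig1, Fhl3 and Nfia. Low depth may contribute, since in the tenth of cells with the fewest UMIs these genes stood higher by a median log2 of 0.41, 1.34 and 0.67 at days 1, 2 and 5, which neither reaches 1 on each day nor stays under 0.5. Inner A runs occurred in 2 of the 13 genes, 1.0 times the share in matched genes, with an interval from 1.92 to 45.4% that decides nothing. Their median transcript length lay at the 97.36 percentile of matched lists and GC content at the 56.4 percentile, so length stays open. The day itself stays open and untested, since day and library cannot be told apart.

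TdTomato in Retnla-like cells stood at 0.169, 0.227 and 0.161 of its level in lining-like cells at days 1, 2 and 5. Free RNA of lining cells would hold lining genes at 1 ratio, but Sparc stood at 0.0407, 0.0438 and 0.0422. TdTomato was at least 2.19 times the median of Sparc, Vsig4 and Olfml3 on every day. These genes are the markers that named lining-like cells, while TdTomato was kept out of the clustering. Cells outside that class are thus picked to be low in the markers but not in TdTomato, so the test cannot decide whether such RNA is the source. Vsig4 alone stood close to TdTomato, at 0.145, 0.172 and 0.158. Expression of the reporter in these cells was not tested and remains a hypothesis.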

How the results depend on the processing

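No paired analysis was possible because each day has 1 library and no test was made. The comparison of lining-like cells with day 0 was not made in the joint clustering, so the alternatives designed for it have no values. Alternatives without the condition on the first 10 genes, with the highest Scrublet scores removed, with each library clustered alone at 200 genes, with all other cells as the junction reference, and expression at 200 genes were chosen after seeing the data. A value was counted as moved when it left the counting interval of the reported one, a narrow limit that takes no account of spread between animals. A value was counted as reversed when its sign changed and the interval of the reported one did not reach 0, so other changes of sign count as moved or as the same. The cause was not tested in any of the cases that follow. By these rules 111 of 308 class shares moved, 87 of 528 ratios of named genes moved and none reversed, 146 of 857 list medians moved and 11 reversed, and 57 of 60 cycling shares moved. Values are given for the class shares, the cycling shares of all cells, the day 0 junction list, the proinflammatory, chemokine and monocyte recruitment lists against day 0, and every reversal by that rule. Which lists have each alternative printed was chosen after seeing the data.

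With at least 200 genes per cell, shares were Retnla-like 0.0814% at day 0, MHC class II-high 10.1% at day 5, osteoclast-like 4.61% at day 5. Further shares were proliferating 4.33% and 1.80% at days 0 and 5. With at least 1000 genes per cell, which left 96 cells at day 0, shares were lining-like 1.04% at day 0, Retnla-like 2.08%, 26.7% and 17.5% at days 0, 1 and 2, MHC class II-high 4.17% and 14.3% at days 0 and 1. Further shares were Arg1-like 0.170% and 9.03% at days 2 and 5, osteoclast-like 3.12% and 5.65% at days 0 and 5, proliferating 1.04% and 2.00% at days 0 and 5. With a mitochondrial share under 5%, shares were lining-like 28.7%, 36.3% and 22.8% at days 1, 2 and 5, Retnla-like 45.4%, 33.9% and 17.1% at days 1, 2 and 5, MHC class II-high 11.4% at day 2. Further shares were monocyte-like 1.02% and 25.9% at days 1 and 5, osteoclast-like 0%, 0% and 0% at days 1, 2 and 5. With doublets kept, shares were Retnla-like 31.1%, 17.8% and 10.6% at days 1, 2 and 5. With resolution 0.5, shares were lining-like 26.5%, 34.2% and 21.2% at days 1, 2 and 5, Retnla-like 39.8%, 29.4% and 15.1% at days 1, 2 and 5, MHC class II-high 9.82% at day 5. Further shares were Arg1-like 13.3% at day 5, osteoclast-like 0.0431%, 0.0368% and 0% at days 1, 2 and 5, proliferating 3.78% at day 5. With resolution 2.0, shares were lining-like 21.4% and 22.2% at days 1 and 2, Retnla-like 25.3%, 15.6% and 9.72% at days 1, 2 and 5, MHC class II-high 14.2% and 10.6% at days 1 and 2. Further shares were Arg1-like 0.538% at day 0. With 15 principal components, shares were lining-like 21.6% at day 1, Retnla-like 35.6% and 22.4% at days 1 and 2, MHC class II-high 11.03% at day 5. Further shares were monocyte-like 1.10% and 14.5% at days 1 and 5, Arg1-like 0%, 0% and 0% at days 1, 2 and 5, osteoclast-like 9.14% at day 5. Further shares were proliferating 5.90% at day 0. With each library clustered alone, shares were lining-like 18.1%, 14.8% and 21.8% at days 0, 1 and 5, Retnla-like 0%, 15.8%, 15.5% and 21.9% at days 0, 1, 2 and 5, MHC class II-high 20.3%, 13.1% and 0% at days 0, 1 and 2. Further shares were monocyte-like 1.84% and 15.8% at days 2 and 5, Arg1-like 0% and 0% at days 1 and 2, osteoclast-like 3.88%, 0%, 7.88% and 0.805% at days 0, 1, 2 and 5. With each library clustered alone and at least 200 genes, shares were lining-like 17.9%, 14.8% and 21.8% at days 0, 1 and 5, Retnla-like 0%, 15.8%, 15.5% and 21.9% at days 0, 1, 2 and 5, MHC class II-high 18.1%, 13.1% and 0% at days 0, 1 and 2. Further shares were monocyte-like 1.84% and 15.8% at days 2 and 5, Arg1-like 0% and 0% at days 1 and 2, osteoclast-like 3.72%, 0%, 7.88% and 0.805% at days 0, 1, 2 and 5. Further shares were proliferating 3.88% at day 0. With no condition on the first 10 genes, shares were lining-like 26.6%, 34.2% and 21.2% at days 1, 2 and 5, Retnla-like 40.6%, 32.9% and 17.2% at days 1, 2 and 5, MHC class II-high 9.54% at day 5. With the cells of highest Scrublet scores removed, shares were Retnla-like 36.0% at day 1, Arg1-like 14.4% at day 5, osteoclast-like 0.112% and 0.793% at days 1 and 5.

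With scaling by median ratio, list medians were chemokines -1.82 (day 1 against day 0) and -1.25 (day 2 against day 0) and -1.38 (day 5 against day 0), glycolysis and hypoxia -0.079 (day 1 against day 0), monocyte recruitment 0.60 (day 1 against day 0). With scaling by median ratio, they were also immediate early and stress -0.036 (day 2 against day 0). By the mean of each cell's CPM, list medians were chemokines -1.43 (day 1 against day 0) and -0.75 (day 2 against day 0) and -1.08 (day 5 against day 0), glycolysis and hypoxia -0.078 (day 1 against day 0), matrix remodelling -0.032 (day 2 against day 0). By the mean of each cell's CPM, they were also cell cycle -0.048 (day 5 against day 0), immediate early and stress 0.10 (day 5 against day 0), Fc receptors -0.0023 (day 2 against day 1). By the mean of each cell's CPM, they were also tight junction and polarity 0.017 (day 5 against day 1). With at least 1000 genes per cell, list medians were chemokines -2.07 (day 1 against day 0) and -1.52 (day 2 against day 0) and -1.46 (day 5 against day 0), lipid handling 0.21 (day 1 against day 0), immediate early and stress -0.22 (day 2 against day 0). With at least 1000 genes per cell, they were also monocyte recruitment 2.43 (day 5 against day 0). With at least 200 genes per cell, list medians were chemokines -1.59 (day 1 against day 0). With no filter on low values, list medians were proinflammatory mediators 0.90 (day 5 against day 0). With doublets kept, list medians were MHC class II in lining-like cells -0.058 (day 2 against day 1). With at least 1000 genes per cell, day 0 counts of 0 make some ratios lower bounds, among them those of Hp, F10 and Plac8 in the monocyte recruitment list. At resolution 2.0 the day 0 junction list had a median of 1.00. Cycling shares at days 0, 1, 2 and 5 were 22.2%, 41.7%, 44.5% and 45.9% without thinning and 1.99%, 1.38%, 1.03% and 2.51% with at least 2 UMIs. Monocyte recruitment at day 5 stayed above 2 and chemokines against day 0 stayed below 0 on each day in every setting. The depth of day 0 limits its classes, and intervals hold no spread between animals.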

Other observations

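Several clusters took no class name. Cluster 3, led by Aqp1, a water channel, and Fxyd2, a regulator of the sodium pump, held 12.2% of cells at day 1, 12.3% at day 2 and 4.68% at day 5, and TdTomato at 361, 428 and 324 CPM. Aqp1 was among the MHC class II-high markers, and the shares of that class leave cluster 3 out. Cluster 6, led by the immediate early gene Egr1 and the chemokine gene Ccl7, held 6.29%, 10.8% and 4.15%, with TdTomato at 519, 694 and 535 CPM. Cluster 14, led by the interferon response genes Ifit3 and Isg15, held 1.01%, 1.44% and 1.24%, with TdTomato at 491, 385 and 494 CPM. Cluster 16, led by Ifitm1 and holding Ccr7, Fscn1 and Ccl22 of mature dendritic cells among its leading genes, held 3.72% at day 5 against 0.0646% and 0.147% at days 1 and 2. Cluster 20, led by the chemokine gene Ccl17, held 34 cells, all of day 5. TdTomato stood at 84.8 CPM in cluster 16 and 135 CPM in cluster 20.

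Against day 1, a reference added after the data were seen, the whole library of day 2 had Cxcl2 as its named higher gene (2.25-fold) and Scand1, a nuclear factor gene, as its named lower gene (2.304-fold). At day 5, Ifitm1 (230.4-fold), Il1b (20.7-fold; 19.4 to 22.1), Spp1 (12.9-fold) and Chil3 (33.4-fold) were higher, and the resident macrophage genes Lyve1 (2.71-fold), Cd163 (2.47-fold) and Pf4 (2.56-fold) were lower. Spp1 was 19.6-fold higher when each cell was weighted equally. Matrix remodelling genes had a median log2 ratio of 2.27 there, with 9 of 16 at least 2-fold higher.

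Haemoglobin RNA stood mostly with Arg1-like cells of day 5, at 740.5 CPM for Hbb-bs and 404 CPM for Hba-a1, against 5.23 and 1.23 CPM in monocyte-like cells of that day. Markers of other cell types were low in the libraries of days 0, 1, 2 and 5. B cell markers stood at 108, 141, 117 and 101 CPM, nearly all Ighm, and endothelial markers at 3.91, 5.83, 8.01 and 13.3 CPM. Neutrophil markers stood at 20.01, 12.2, 14.5 and 48.4 CPM, and NK or T cell markers at 9.66 CPM at day 0 and 0.413 CPM at day 2, with none listed at days 1 and 5, which is not a measured 0. Where listed, mast cell, basophil or eosinophil, and muscle, cartilage or keratinocyte markers each stood at 2.83 CPM or less.

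With each library clustered alone, lining-like cells against those of day 0 had chemokine medians of -3.42, -2.23 and -1.51 at days 1, 2 and 5, MHC class II medians of -2.85, -2.24 and -2.51, proinflammatory medians of -3.73, -1.68 and -0.071, and immediate early and stress medians of -1.21, -0.90 and 0.038. Whether RNA of other cells also stands in day 0 lining-like cells was not tested, so these values may not be their own.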
